A study of Homo sapiens with 6 samples.

How the data were processed

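RNA of a cell line labelled HepG2 was sequenced in 6 libraries, 3 WT and 3 sgPARP1, and each library's group and replicate number were taken from its title. Libraries were made with a kit for messenger RNA, per the labels' protocols. The labels do not say whether the 3 libraries of a group come from separate cultures, nor whether the sgPARP1 cells are a clone or a pool, so p-values measure only the spread between these libraries, which may be technical.

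The authors deposited a table of FPKM, reads scaled to gene length and library size, with Ensembl gene IDs, symbols, coordinates and lengths for 62753 genes, 28336 of them above 0 in a library, besides 1 emptied line. The submitters' processing notes name the genome builds hg38, GRCm38 and mm10 with no role. The aligner, the counting tool, the use of strand in counting and their versions are not given in the sources used here. Of the gene IDs, 58260 are shared with the GENCODE release 29 annotation, and 99.9% of these overlap their gene there on the same chromosome, so coordinates are human and given as hg38. Reads from a gene and from an overlapping gene on the other strand, or from close paralogs and pseudogenes, cannot be told apart in these values.

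FPKM times gene length came in whole multiples of 1 step per library in the deposited table. All values of up to 200 reads (12911 to 13113 per library) lay within 0.02 of a whole read, which gave 14842498 to 17305129 reads per library. Mitochondrial genes took 4.18% to 4.49% of them. The precision follows the level: the median standard error of a log2 fold change was 0.122 at a mean of 0.5 to 1 FPKM (a median of 25.8 reads) and 0.049 from 20 FPKM on. Libraries of one group differed by more than counting noise, with a chi-square per gene of 3.49 to 7.27 over genes with at least 20 reads, against 10.4 to 18.9 between groups, so no library was taken for a duplicate. The first principal component held 36.5% of the variance and separated the groups.

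Values were tested as log2(FPKM + 1), a pseudocount of 1, in genes with a mean of at least 0.5 FPKM over the 6 libraries, with limma's moderated test with a trend (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. Because the table holds FPKM and no counts, this was the test fixed for that case. Percent decreases and fold values of single genes are ratios of mean FPKM, and the counts of genes changed at least 2-fold are on the log2 scale tested. Gene lists, 32 in all, were fixed before the data were examined, as were the tests and most alternatives, and 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera called 12 lists, 7 higher and 5 lower. None of the calls held with an estimated correlation, and fry, which asks whether a list's genes move one way and does not compare them with other genes, called 17. The estimate was below the preset 0.01 for DNA replication (−5.49e-05), both lipid synthesis lists (0.00348 and −0.0254), NRF2 (0.00817), heat shock (−0.0421) and NF-kB (−0.0482). For these lists a larger correlation is not what ended the call. The other called lists had larger estimates, up to 0.313 for glycolysis.

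Named genes were PARP1, then the 10 protein-coding genes with the largest and the 10 with the smallest log2 fold change among genes past the test whose groups did not overlap, then up to 4 members of each list with the largest absolute log2 fold change past the test, filled up to 2 with the most abundant members where fewer than 2 passed. Genes named outside this rule, such as IFITM1, ME1, HSD17B7, KRT8, ANXA4, and the hepatocyte genes listed at 0, were chosen after their values were seen. Some genes that the rule takes are not reported here.

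The test was tried on simulated libraries with 200 changed genes. It recovered 0% of genes changed 1.2-fold, 61.5% of those changed 1.5-fold and 79% of those changed 2-fold, with 5.4% and 7.1% of calls false at 1.5-fold and 2-fold. All simulated genes had the same dispersion of 0.002, and far fewer changed than the 1048 called in the data. These shares therefore need not hold for the data, where CCNB1, for example, passed at 1.18-fold. Camera recovered a list shifted 1.2-fold (adjusted p = 2.36e-44, and 0.00242 with an estimated correlation) and called 0 of 27 other lists. The form with an estimated correlation thus gave a far larger p even for genes drawn independently. Genes were drawn independently in the simulation. In the data the estimated correlation reached 0.313 among the called lists, for glycolysis, and 0.574 for the mitochondrially encoded genes, which were not called. The simulation therefore cannot show how often camera calls a list falsely when its genes move together. A simulated shift of −0.20 over chromosome 21 came back as −0.18, with no other autosome beyond 0.0148 in absolute value.

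The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, TPM, limma without a trend and with a robust prior, a replicate block, and leaving out each library. Chosen after seeing the data were limma's voom on the recovered reads, with at least 10 reads on average, and a loess correction of each library for GC content. The positions of genes were examined after the data were seen, in 30-gene windows moved by 10 genes. GC content came from GENCODE release 29 transcripts, which covered 99.9% of the genes in that step. DESeq2 and edgeR were not run, since the table holds no counts. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.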

Results

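Messenger RNA of cells labelled as HepG2, a line derived from a human hepatocellular carcinoma, was sequenced in 2 groups of 3 libraries. The WT group holds unedited cells. In the sgPARP1 group the gene for poly(ADP-ribose) polymerase 1, an enzyme that binds DNA breaks and marks proteins with ADP-ribose chains, had been targeted with CRISPR-Cas9. The comparison asks how the transcriptome differs once PARP1 is knocked out. The WT libraries hold 17305129, 17179935 and 14842498 reads assigned to genes and the sgPARP1 libraries 15633365, 15383400 and 17197118, as worked out from the deposited FPKM values, and each library has a read in 21437 to 21903 genes. Fold changes are sgPARP1 over WT, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

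PARP1 (ENSG00000143799, minus strand of chromosome 1, 226360210 to 226408154 in hg38) fell from 31.6 ± 0.17 FPKM in WT to 4.31 ± 0.083 FPKM in sgPARP1 (mean ± SD, n = 3 each), a decrease of 86.4%. The 3 WT values were 31.8, 31.5 and 31.5 FPKM and the 3 sgPARP1 values 4.31, 4.23 and 4.39 FPKM, from 8738 to 10110 reads per WT library and 1198 to 1392 per sgPARP1 library. The log2 fold change was −2.62 with a standard error of 0.037 (limma, Benjamini-Hochberg adjusted p = 7.3e-07). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. The other 17 tested genes of the PARP family and of ADP-ribose turnover did not pass the test, among them ADPRS at a log2 fold change of −0.08, and the count is the same when adjusted over the list alone. The median of this list was 0.03 and its mean −0.15, the mean being set by PARP1, and camera, pointing down, did not call it (adjusted p = 0.663).

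On the log2(FPKM + 1) scale the genes that rose most were PPDPFL, from 4.35 ± 0.26 to 40.9 ± 0.53 FPKM, and CGA, the alpha subunit shared by the glycoprotein hormones, from 4.66 ± 0.49 to 33.1 ± 1.6 FPKM. The cancer-testis antigens MAGEA1 and XAGE2 rose 3.77-fold and 3.40-fold, the gap junction protein GJA1 3.6-fold, the sorting receptor SORL1 5.40-fold and OLFM1 3.33-fold. MROH2A, near 0 in WT at 0.155 FPKM, reached 2.67 FPKM, a 17.2-fold rise in mean FPKM. Among the genes that fell, the protease inhibitor SPINK6 went from 15.1 ± 3.0 to 0.174 ± 0.067 FPKM, the proteoglycan LUM from 9.15 ± 0.49 to 1.04 ± 0.26 FPKM and SLFN11, a factor that stalls stressed replication forks, from 1.39 ± 0.15 to 0.0209 ± 0.011 FPKM. The sgPARP1 values of SPINK6 and SLFN11 rest on 1 to 3 reads per library. The calcium-binding protein S100A16 fell by 70.2%, the prostaglandin E synthase PTGES by 62.6%, the focal adhesion protein TNS1 by 68.1%, ECM1 by 75.7% and the neuropeptide Y receptor NPY4R by 75.9%. Reads of MAGEA1, XAGE2 and NPY4R can be shared with near-identical relatives, so their values are uncertain.

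**Figure D1:**
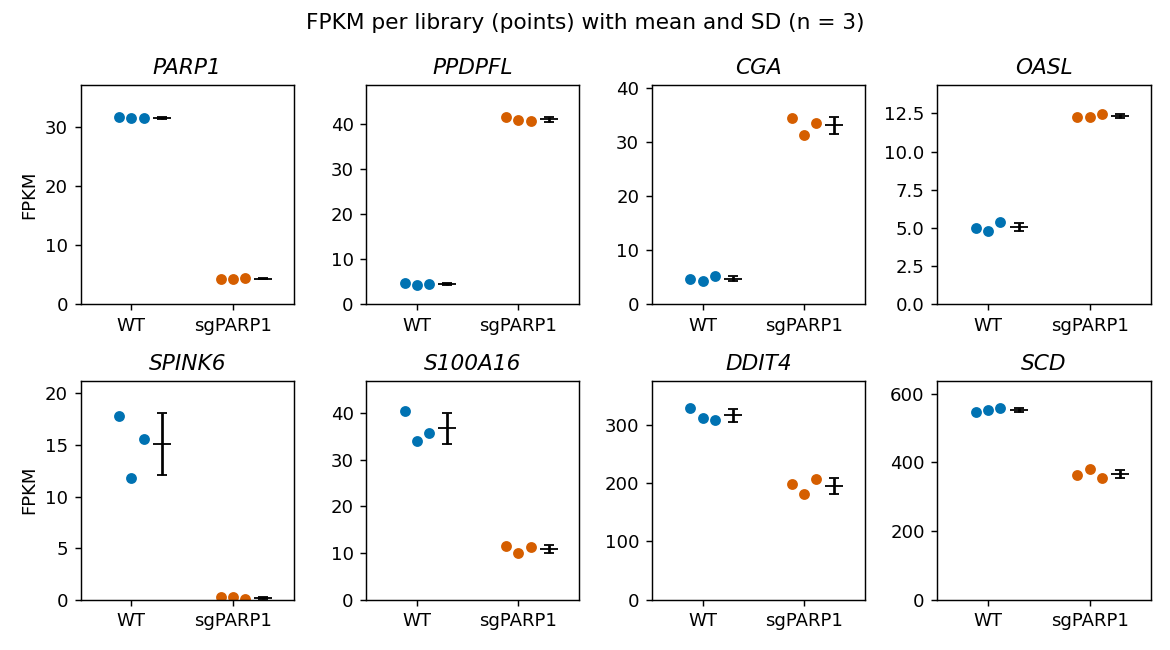
FPKM of 8 genes in each library (points: 3 WT, blue, and 3 sgPARP1, orange), with the mean and SD of each group in black. PARP1 lies at 31.5 to 31.8 FPKM in WT and 4.23 to 4.39 FPKM in sgPARP1. No group overlaps the other in any of the 8 genes, which were all picked from genes past the test.

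Of 13167 genes tested, 1048 changed (8.0%), 463 higher and 585 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 55 of these changed at least 2-fold on the log2(FPKM + 1) scale, 28 higher and 27 lower. This number depends on the scale: the genes changed at least 2-fold were 125 with a pseudocount of 0.1, 112 with TPM and 260 with voom. Most changes were small: 764 of the 1048 had an absolute log2 fold change under 0.5, and the median was 0.35. Protein-coding genes made up 429 of the higher and 534 of the lower genes. The 3 values of one group all lay outside those of the other in 31.1% of tested genes, where chance gives 10%. The count depends on every library: it was 557, 413 and 544 without WT replicate 1, 2 or 3, and 417, 654 and 626 without sgPARP1 replicate 1, 2 or 3. It was 587 with no filter on low values, 1686 with voom on the recovered reads and 1657 after a correction for GC content.

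**Figure D2:**
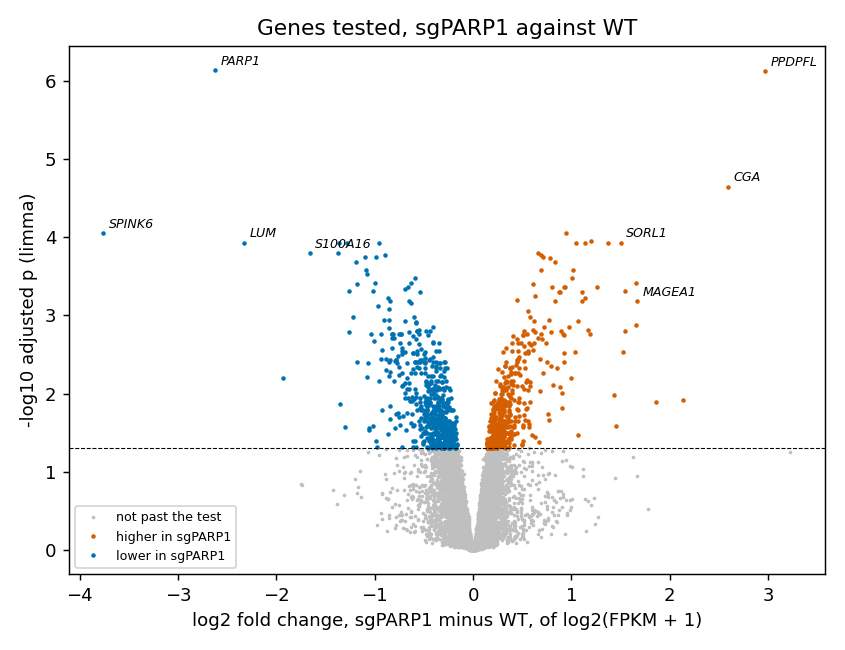
Log2 fold change (sgPARP1 minus WT, of log2(FPKM + 1)) of the 13167 tested genes against −log10 of the limma adjusted p. Orange points are the 463 higher and blue points the 585 lower genes, and the dashed line is the threshold of 0.05.

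Genes of the hypoxia response were lower in sgPARP1 as a group. Of 19 tested, 11 fell, 8 did not pass and none rose, and 15 fell when adjusted over the list alone. The stanniocalcin STC2 fell by 48.1%, from 13.0 ± 1.2 to 6.76 ± 0.05 FPKM, the mTORC1 inhibitor DDIT4 by 38.2%, from 316 ± 11 to 196 ± 13 FPKM, the angiogenic factor VEGFA by 28.1% and INSIG2 by 31.6%. Genes of glucose transport and glycolysis followed the same direction. Of 22 genes tested 9 fell and none rose (also 9 when adjusted over the list alone), led by the glucose transporters SLC2A3, down by 58.4%, and SLC2A1, down by 26.5%, hexokinase HK1, down by 35.5%, and PFKFB4, down by 27.2%. Camera called both lists lower (adjusted p = 1.82e-09 for hypoxia and 3.42e-05 for glycolysis). Neither call held with an estimated correlation (adjusted p = 0.0676 and adjusted p = 0.337 with an estimated correlation). The counts of 0 higher genes are the same at an unadjusted p under 0.05, where 15 hypoxia and 9 glycolysis genes were lower, and by voom, which called 14 and 9 lower.

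Several genes of lipid synthesis were lower too. SCD, the desaturase that makes monounsaturated fatty acids, fell from 552 ± 6.4 to 366 ± 13 FPKM, fatty acid synthase FASN from 175 ± 12 to 127 ± 5.9 FPKM, the transcription factor SREBF1 by 31.6% and the acetyl-CoA synthetase ACSS2 by 28.9%. In all, 5 of 17 fatty acid and triglyceride synthesis genes fell and ME1 rose (6 and 1 when adjusted over the list alone). Of 22 genes of the cholesterol synthesis list 5 fell and 1 rose (7 and 1 when adjusted over the list alone): INSIG1 fell by 38.3%, FDPS by 23.3% and HSD17B7 by 22.4%, while SC5D, a late step of the pathway, rose 2.51-fold. Camera called both lists lower (adjusted p = 0.000503 for fatty acid and 0.000308 for cholesterol synthesis), with adjusted p = 0.0676 for each with an estimated correlation. FASN and FDPS lie in stretches of chromosomes 17 and 1 whose genes were lower together. Fatty acid oxidation and ketogenesis was not called as a list (camera adjusted p = 0.461): 4 of 23 genes fell, by the main count and when adjusted over the list alone, with a median of 0.01, a mean of −0.08 and a test that points down. PDK4, the kinase that holds back pyruvate oxidation, fell by 61.9%, ACADS by 24.2%, ACADVL by 20% and CPT1A by 11.7%.

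Interferon-stimulated genes were higher. Of 25 tested, 12 rose, 12 did not pass and IFITM1 fell (16 higher and 3 lower when adjusted over the list alone). OASL rose 2.44-fold, from 5.05 ± 0.29 to 12.3 ± 0.1 FPKM, the antiviral enzyme RSAD2 4.36-fold from a low level of 0.367 FPKM, IFI44 1.92-fold and IFI6 1.68-fold, from 24.6 ± 1.1 to 41.4 ± 3.0 FPKM. Camera called the list higher (adjusted p = 9.22e-06), though not with an estimated correlation (adjusted p = 0.0676 with an estimated correlation). Of 15 NF-kB and inflammatory targets 5 rose and 1 fell (7 and 2 when adjusted over the list alone): the cytokine IL32 rose 2.23-fold, the adhesion molecule ICAM1 2.13-fold and the feedback inhibitor TNFAIP3 1.40-fold, while LIF fell by 66.3%. The list NF-kB and inflammatory targets passed camera narrowly (adjusted p = 0.0471) and not with an estimated correlation (adjusted p = 0.212 with an estimated correlation), and the call was also lost without WT replicate 2 (adjusted p = 0.0551), without sgPARP1 replicate 3 (adjusted p = 0.0722), with voom (adjusted p = 0.0937) and with no filter on low values (adjusted p = 0.457).

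Cell cycle genes were slightly higher. Of 29 G2/M and mitosis genes 8 rose and none fell (12 and 0 when adjusted over the list alone), among them the cyclins CCNB1, 1.18-fold from 103 ± 1.3 to 121 ± 1.9 FPKM, CCNB2, 1.18-fold, and CCNA2, 1.14-fold, and the kinesin KIF23, 1.2-fold. Of 29 DNA replication and G1/S genes 3 rose and none fell (8 and 0 when adjusted over the list alone): the ribonucleotide reductase subunit RRM2 rose 1.23-fold, GINS1 1.18-fold and GINS2 1.16-fold. Camera called both lists higher (adjusted p = 1.59e-07 and 3.42e-05), with adjusted p = 0.0676 for each with an estimated correlation. At an unadjusted p under 0.05, 17 and 12 genes of the 2 lists were higher and none lower, and voom called 8 and 6 higher and none lower. Among p53 target genes, which were not called as a list (camera adjusted p = 0.422), 2 of 26 fell and 2 rose (4 and 6 when adjusted over the list alone). The stress cytokine GDF15 fell by 57.3%, from 42.5 ± 2.6 to 18.2 ± 1.6 FPKM, and the cell cycle inhibitor CDKN1A by 34.3%, from 63.5 ± 2.1 to 41.7 ± 5.3 FPKM, whereas PLK2 rose 1.40-fold and BTG2 1.18-fold. The median of this list was 0.04 and its mean −0.01, and the test points up.

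No gene of the 3 DNA repair lists passed limma, either over all genes or when adjusted over the list alone. None of 21 homologous recombination genes passed limma (6 higher and 0 lower at an unadjusted p under 0.05; voom called 2 higher), yet they leaned upward together, with a median log2 fold change of 0.10, and EXO1 and RBBP8 stood at 0.22 and 0.09. Camera called this list higher (adjusted p = 0.00819), with adjusted p = 0.376 with an estimated correlation, and fry did not call it (adjusted p = 0.0596). None of 20 base excision and single-strand break repair genes passed limma (3 higher at an unadjusted p under 0.05, 1 higher by voom), FEN1 and UNG being at 0.14 and 0.16 (camera adjusted p = 0.0597). None of 13 end joining genes passed limma, at an unadjusted p under 0.05 or by voom, and XRCC6 and XRCC5, which form the Ku heterodimer, were at 0.01 and −0.01 (camera adjusted p = 0.694).

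**Figure D3:**
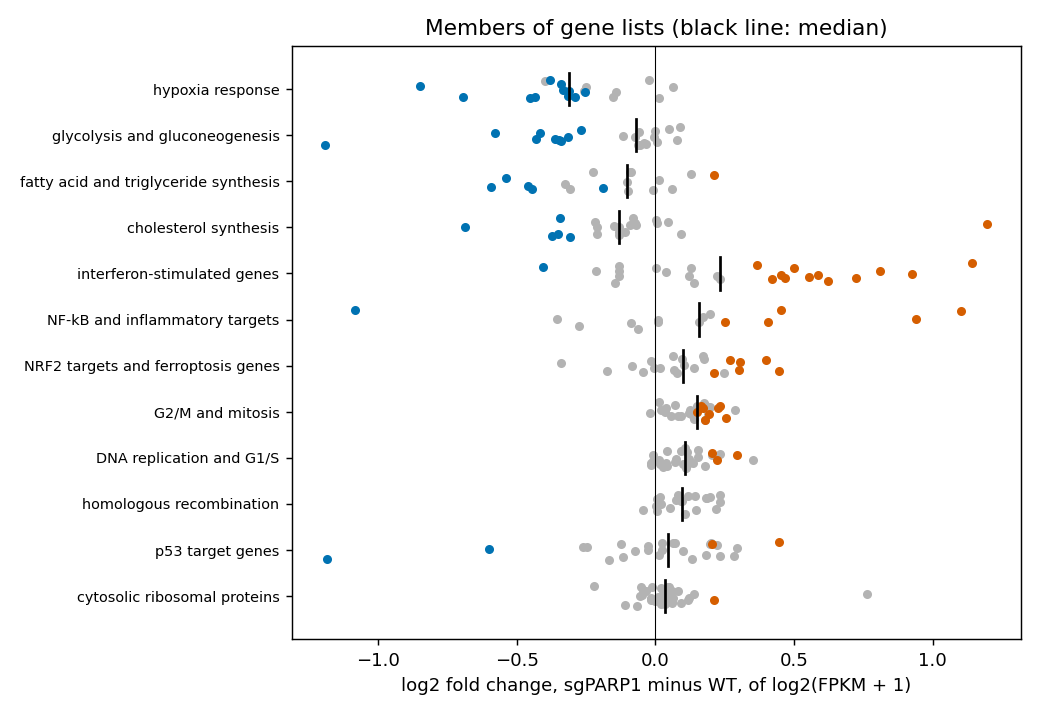
Log2 fold change (sgPARP1 minus WT, of log2(FPKM + 1)) of each tested member of 12 gene lists. Each point is a gene, orange if it rose, blue if it fell and grey if it did not pass the test, and black lines are list medians, −0.31 for the hypoxia response and 0.23 for interferon-stimulated genes.

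Antioxidant and chaperone genes were higher. Of 22 NRF2 targets and ferroptosis genes 6 rose and none fell (10 and 1 when adjusted over the list alone): the quinone reductase NQO1 rose 1.37-fold, the thioredoxin reductase TXNRD1 from 185 ± 5.3 to 244 ± 8.1 FPKM, SRXN1 1.27-fold and the transferrin receptor TFRC 1.24-fold. Of 13 heat shock genes 4 rose and none fell, also when adjusted over the list alone, with HSPA8 at 1.14-fold, DNAJB1 at 1.15-fold, DNAJA1 at 1.16-fold and DNAJB4 at 1.25-fold. Camera called both lists higher (adjusted p = 0.000687 and 0.00617), with adjusted p = 0.0774 and adjusted p = 0.107 with an estimated correlation. At an unadjusted p under 0.05, 2 NRF2 and 1 heat shock genes were lower, and voom called 1 and 0 lower. The amino acid and unfolded protein response was not called (camera adjusted p = 0.70): 1 of 27 rose, DNAJB9 at 1.54-fold, and SHMT2 fell by 15.4% (4 and 6 when adjusted over the list alone). DNAJB9 lies within a stretch of chromosome 7 whose genes were higher together.

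Genes of the list replication-dependent histones were lower, with 3 of 9 fallen and none risen, also when adjusted over the list alone. H3C2 fell by 33.4%, H3C10 by 27.5% and H2BC5 by 13.1%, all members of multigene families whose reads can be shared. H3C2 rests on 30 to 60 reads per library. How fully the kit for messenger RNA takes up these histone RNAs was not tested, so the values need not follow their total level. Camera called the list lower (adjusted p = 0.017), with adjusted p = 0.33 with an estimated correlation. The call was also lost with voom (adjusted p = 0.063), after the GC correction (adjusted p = 0.0989) and without WT replicate 3 or sgPARP1 replicate 2 (adjusted p = 0.0857 and 0.0733). At an unadjusted p under 0.05 no histone gene was higher, nor was any by voom. Of 37 cytosolic ribosomal protein genes RPL7 alone passed limma, rising 1.16-fold, also when adjusted over the list alone (camera adjusted p = 0.0971), and RPS9 was listed at 0 in all 6 libraries. Of 13 mitochondrially encoded genes MT-ND4 alone passed, falling by 10.4%, also when adjusted over the list alone (camera adjusted p = 0.335, pointing down, median −0.03, mean 0.02). In NAD metabolism 2 of 21 genes fell, KYNU by 19.3% and the deacetylase SIRT7 by 17.0% (5 when adjusted over the list alone; camera adjusted p = 0.295, pointing down, with a median of −0.02 and a mean of 0.02). SIRT7 lies in the stretch of chromosome 17 whose genes were lower together.

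Matrix, adhesion and signalling genes moved in both directions. On the mesenchymal side 5 of 17 tested markers fell and 2 rose (5 and 3 when adjusted over the list alone; camera adjusted p = 0.115): the fibronectin receptor subunit ITGA5 fell by 58.8%, TGFB1 by 41.4% and TGFBI by 36.8%, while TAGLN rose 3.10-fold. On the epithelial side 4 of 13 fell and 1 rose (5 and 3 when adjusted over the list alone; camera adjusted p = 0.201), with MUC1 down by 34.5%, DSP by 21.9% and DSG2 by 20.7% and PKP2 up 1.29-fold. MUC1 lies in the lower stretch of chromosome 1, and KRT8, which also fell, has many pseudogenes. Among 17 AP-1 and immediate-early genes 4 fell and 2 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.115): FOSL1 fell by 35.7% and NR4A1 by 31.1%, while the matricellular genes CCN2 and CCN1 rose 2.55-fold and 1.62-fold. Of 8 Wnt targets 3 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.694), with the Wnt antagonist DKK1 down by 56.0%, TBX3 down by 29%, BAMBI up 1.34-fold and GLUL up 1.37-fold.

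Most genes for proteins that hepatocytes secrete were near 0 or listed at 0 in both groups. Of 31 genes for proteins that hepatocytes secrete, 28 had a mean under 0.5 FPKM, and ALB, AFP, APOB, TTR and SERPINA1 were listed at 0 in all 6 libraries. Of the 28, 13 were listed at 0 throughout and 15 had a read in some library. A listed 0 need not be a real one, since the ribosomal protein gene RPS9 was at 0 too. The 31 genes together took at most 0.012% of a library's reads. Of the 3 secreted protein genes tested, complement C3 fell from 9.19 ± 0.73 to 5.14 ± 0.25 FPKM, also when adjusted over the list alone, and VTN was at 1.34 and 1.71 FPKM. Of 21 hepatocyte transcription factor genes 8 had a mean of at least 1 FPKM, the highest at 46.8 FPKM. Of these 8, which were tested, CEBPA fell by 38.2% and TBX3 by 29% and none rose (5 fell when adjusted over the list alone; camera adjusted p = 0.0825; 5 lower and 0 higher both at an unadjusted p under 0.05 and by voom). None of 8 fetal liver and liver cancer markers passed limma, at an unadjusted p under 0.05, when adjusted over the list alone or by voom, with CD24 and H19 at −0.07 and −0.10 (camera adjusted p = 0.957, pointing up, with a median of −0.00276 and a mean of −0.00581). H19 varied widely between sgPARP1 libraries, at 52.5, 26.2 and 80.4 FPKM (standard error of the log2 fold change 0.387), so a change of it can be neither read nor excluded. Of 3 bile acid and drug metabolism genes the exporter ABCC2 fell, from 14.9 ± 0.45 to 7.82 ± 0.60 FPKM, also when adjusted over the list alone, and CYP1B1 was at 0.09 (list median 0.02, mean −0.25).

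Markers of other cells give the following. Of 6 fibroblast and stellate cell markers LUM and DCN, which are neighbours on chromosome 12, fell and none rose (2 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.262, pointing down, with a median of 0.01 and a mean of −0.44; 1 higher at an unadjusted p under 0.05 and 1 by voom). CSF1R, the only blood and endothelial marker at a testable level, was at 1.52 ± 0.17 and 0.937 ± 0.15 FPKM and passed when adjusted over the list alone, not over all genes. The keratins KRT7, at 279 ± 12 and 254 ± 14 FPKM, and KRT17, at 200 ± 14 and 237 ± 20 FPKM, were abundant in both groups. With ANXA4 they make up the 3 tested markers of cholangiocytes and other epithelia, of which none passed over all genes and 1 was higher when adjusted over the list alone (1 higher and 1 lower at an unadjusted p under 0.05, 1 higher by voom).

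Fold changes followed the position of genes on some chromosomes. Among 6235 protein-coding genes with a mean of at least 5 FPKM, 45 of the 48 on chromosome 21 were lower in sgPARP1, with a median log2 fold change of −0.17. In a window of chromosome 7 (102464956 to 128458418) 29 of 30 genes were higher, with a median of 0.21. On chromosome 1, 241 of 317 genes of the long arm, which holds PARP1 (144421390 to 248859144, beyond the widest stretch without a gene used here), were lower, with a median of −0.07, against 141 of 395 genes of the other arm, with a median of 0.06. The lowest window of that arm (154581695 to 156212796) had a median of −0.16 and 28 of 30 genes lower. A window of chromosome 17 (81539885 to 82490537) stood at −0.15, and at −0.06 after the GC correction. Of 568 windows of 30 genes, 5 were lower and 4 higher than any window in 1000 shuffled gene orders, whose largest absolute median was 0.14. Neighbouring windows share genes, so these are not separate findings: the 4 higher ones follow each other on chromosome 7. Fold changes also leaned on GC content, with a correlation of −0.237 across the 6235 genes. On chromosome 19, with a median GC content of 60.3%, WT replicate 1 stood at 0.08 and sgPARP1 replicate 2 at −0.13 (median deviation), and the median log2 fold change went from −0.04 to 0.01 with the GC correction. Of the lists that camera called, the histones alone lost their call with it, and the list base excision and single-strand break repair gained one (adjusted p = 0.0142). Without chromosome 21 and the chromosome 7 window 1002 genes changed, 441 higher and 561 lower.

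**Figure D4:**
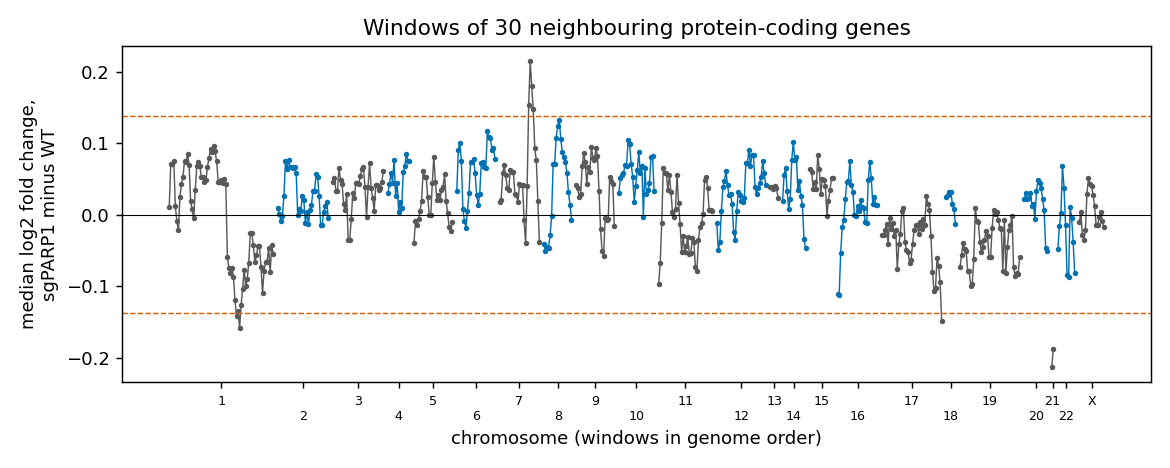
Median log2 fold change (sgPARP1 minus WT) of 568 windows of 30 neighbouring protein-coding genes in genome order, with chromosomes in alternating colours. Dashed lines mark the largest absolute window median in 1000 shuffled gene orders, 0.14, and windows on chromosomes 1, 7, 17 and 21 lie beyond it.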

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

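The fits with voom and with GC-corrected values were chosen only after the results were seen. PARP1 was lower and past the threshold under every alternative, from −2.88 with voom to −2.61 without sgPARP1 replicate 2. All 1048 changed genes that an alternative could test kept their sign. Leaving out 1 library gave 413 to 654 changed genes, 172 to 285 higher and 229 to 373 lower, with the fewest without WT replicate 2. With no filter on low values 587 genes changed (278 higher, 309 lower), 28336 genes then being tested. Voom called 1686 (1003 lower), and GC-corrected values gave 1657 (genes higher: 820), with 979 and 992 shared with the 1048. The number changed at least 2-fold was 125 and 93 with pseudocounts of 0.1 and 0.5, 112 with TPM, 260 with voom and 30 among genes with a mean of at least 5 FPKM. With the replicate number as a block 550 genes changed (232 higher, 318 lower), 510 of them shared, but the numbers do not pair the libraries: same-numbered libraries had correlations of deviations of 0.0408, 0.0813 and −0.0262. The block also ended the NF-kB list's call. Gene lists called were 0 with an estimated correlation. Other fits gained list calls, among them no filter on low values (4 gained, 1 lost) and a mean of at least 5 FPKM (3 gained, 0 lost). Without sgPARP1 replicate 2, 3 lists gained and 1 lost a call. The cause of these shifts was not tested. Median-of-ratios scaling moved nothing, since the FPKM already carry such a scaling. DESeq2 and edgeR were not run on FPKM. Of genes at 0.5 to 1 FPKM 2.17% were called, against 12.6% from 20 FPKM on; depth and pseudocount were not told apart.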

Other observations

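The tests on other splits of the libraries, on single libraries, on 4 consecutive parts of chromosome 21, on the arm of chromosome 1 between centromere and PARP1, on the hepatocyte genes and on the YAP and TAZ targets with an estimated correlation were chosen only after the result was seen, as were the genes named in the next 2 paragraphs.

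Some single genes outside the fixed lists rose. The thrombospondin THBS1 went from 11.1 ± 0.22 to 23.9 ± 1.1 FPKM, the tropomyosin TPM1 from 13.3 ± 0.13 to 22.3 ± 0.38 FPKM, the myosin light chain MYL9 from 46.7 ± 3.1 to 72.2 ± 3.7 FPKM, caldesmon CALD1 1.49-fold and the LIM protein AJUBA 1.56-fold, but whether genes of the contractile cytoskeleton or of cell-matrix contact moved as a group was not tested, and ITGA5, TNS1 and TGFBI fell. THBS1, CCN1 and CCN2 are known targets of YAP and TAZ. A general rise of YAP and TAZ targets was one hypothesis, tested on 14 such genes listed before their values were seen. Their median log2 fold change was 0.16, with 12 of the 14 above 0, which passed camera at 0.05 with a preset and with an estimated correlation. LATS2 and CRIM1 rose by limma, and F3 stood at −0.30. A further condition set beforehand, that 1 in 4 pass limma as higher, was not met, with 2 of the 3.5 it asks for, a shortfall within the binomial spread of that count (SD 1.62, a spread allowed for only after the result was seen). The conditions thus point different ways, and a general rise of these targets is left open.

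Some of the largest changes sit side by side in the genome. SC5D and SORL1 are neighbours on chromosome 11 (121292681 to 121633763 together) and rose 2.51-fold and 5.40-fold, while the nearest tested genes, TBCEL and UBASH3B, had log2 fold changes of −0.06 and −0.50, the latter a fall. LUM and DCN are neighbours on chromosome 12, and both fell, DCN from 1.07 to 0.296 FPKM. Within the cancer-testis genes MAGEA11 rose 3.35-fold besides MAGEA1 and XAGE2, but MAGEA12, MAGEB2, PAGE1 and CTAG2 did not pass the test. On chromosome 1 the S100 genes S100A16, S100A4, S100A11 and S100A2 fell, S100A4 from 338 ± 9.7 to 254 ± 4.7 FPKM, while S100A10, S100A13, S100A3 and S100A6 did not pass; they lie in or beside a stretch of 1q whose genes were lower together. Among mitochondrial RNAs the 12S rRNA MT-RNR1 rose 1.30-fold and the tRNA gene MT-TL2 2.96-fold, a value from a very short gene, while MT-RNR2 did not pass. Of 21 mitochondrial tRNA genes tested, 4 were higher and 1 lower.

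Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, namely the real one itself, with 1048 genes against at most 3 in any other. With 10 splits a share under 0.05 cannot be reached.

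Chromosome 21 was lower nearly throughout and a part of 7q higher. GC content does not account for either: after the GC correction the medians were −0.17 and 0.22, beyond the largest absolute median of 0.14 in shuffled gene orders. No single library sets them, since the smallest absolute median without 1 library was 0.15. The medians of 4 consecutive parts of the chromosome 21 genes were all below 0, from −0.241 at the centromeric end to −0.0698 (standard error 0.0339) at the telomeric end, each by more than 2 standard errors. After the GC correction the last part stood at −0.0366, within 2 standard errors of 0 (0.0318 each), and the other 3 between −0.249 and −0.177. A lower copy number of all or most of chromosome 21 in a share of the sgPARP1 cells may be present, but these values do not decide it; the GC correction was added to this test after the result was seen. DNA was not analysed here, and whether such a difference came with the editing, with cloning or with passage stays open.

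PARP1 lies far out on 1q, and Cas9 breaks can cost the arm beyond the cut. The 43 genes beyond PARP1 had a median log2 fold change of −0.0442, which a loss of that part in most cells would exceed. A loss that begins at the cut would also leave the rest of the arm at 0, but the 273 genes between the centromere and PARP1 had a median of −0.0796, at least as low. A shift of the whole arm, for example from fewer copies of 1q in a share of the cells, may be present and was not tested apart from these values.

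In the libraries labelled HepG2 most genes for proteins that hepatocytes secrete were under 0.5 FPKM with few reads or listed at 0, and ALB and AFP were listed at 0. Failed estimates listed as 0 in all libraries cannot explain the 15 of the 28 secreted protein genes under 0.5 FPKM that have a read in some library. This follows from how the 15 were chosen and is no test. Their values in single libraries can be 0 too: 125 values of the whole list were 0, those of the genes at 0 throughout included. The 13 genes at 0 in all libraries, ALB among them, cannot be settled one by one. Of 38 ribosomal protein genes 1 (2.63%) was listed at 0 as well, so a listed 0 need not be a real one. Failures at that rate would leave far fewer than 13 of the 31 genes at 0, which argues against failed estimates for the 13 as a set. A loss through PARP1 editing does not account for the low values, since in WT only 2 of the 18 secreted protein genes with reads reached 1 FPKM. Of 52 secreted protein and transcription factor genes 10 reached 1 FPKM in WT. That is 31.2% of the 32 with reads, above the 1 in 4 allowed for, but under 1 in 4 of all 52. Only 2 of the 10 code for secreted proteins. The rule also asked that ALB have reads. With ALB listed at 0 it could not have pointed to another line, whatever that share. The rule therefore decides nothing, and it was made stricter after the result was seen, with genes listed at 0 left out. Cells of another line than the label names, and HepG2 cells that had lost hepatocyte expression before the experiment, are left open. Both groups show the low values, and how far the comparison speaks for liver cells is open.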
